A study of Danio rerio with 12 samples.

How the data were processed

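Total RNA of whole zebrafish embryos was sequenced after removal of ribosomal RNA, with strand-specific libraries and ERCC spike-in RNA added, per the labels' protocols. Each of the 12 libraries held a pool of 30 embryos from 1 clutch, and each clutch came from a single pairwise mating. There were 4 groups of 3 libraries: mon at 22 hpf, siblings at 22 hpf, mon at 30 hpf and siblings at 30 hpf. Embryos were sorted on the fluorescence of a drl reporter shortly before the first collection, so the groups rest on phenotype. The sibling libraries are labelled wild-type/het.

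The authors deposited 1 table of raw read counts per gene, with 32520 Ensembl gene IDs and 12 library columns. Per the submitters' processing notes, which give no role or order, FastQC, cutadapt, TopHat2 2.0.11, Cufflinks 2.2.1 and HTSeq were used with the genome build GRCz11. The annotation release, the strand setting of the counting and any filters are not given in the sources used here. Overlapping or antisense genes, and near-identical copies such as the globins, may share or lose reads in such counting. The table held 0 lines that name no gene, 0 ERCC lines and 0 columns that could not be tied to a sample.

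Symbols were matched to 29201 of the 32520 IDs (89.8%). Symbols in capitals are those of an orthologue and can be shared by several zebrafish copies, so the ID is printed beside them. A symbol in capitals was shown in lower case for 7497 IDs where a zebrafish gene of that name exists in the RefSeq gene table of the GRCz12tu assembly. That assembly differs from the build of the counts, so no coordinate is given, and it was used only for names and for the order of genes. The genes that could be named in it made up 64.7% of those tested.

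Totals ran from 18233320 to 23135676 counts per library. Pairs of libraries within a group differed by a chi-square of 6.69 to 10.3 per gene, so no library was a repeat of another of its group. The most abundant gene took 3.83 to 5.09% of a library. With 3 counts over a group as the floor, a gene with no read in a group was given a lower bound of its fold. Floors cover counting error only, since PCR copies were not told apart. In a principal component analysis of the 1000 most variable genes the first component held 75.6% of the variance and separated the stages, the second held 9.7% and separated the genotypes.

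The main test was fixed before the data were examined, as were the gene lists, the rule for named genes and the alternatives unless said otherwise. It was the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, on TMM-scaled counts of the 21778 genes kept by filterByExpr. All 12 libraries entered 1 fit with the 4 groups, which left 8 residual degrees of freedom and a common biological coefficient of variation of 0.142. The contrasts were mon against sibling at 22 hpf, the same at 30 hpf, the difference between these effects, and 30 against 22 hpf within siblings and within mon. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene was called at an adjusted p under 0.05. The 2 mon comparisons share no library.

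The libraries pair by clutch, since the labels give the clutch of each and a clutch is the offspring of 1 mating. Deviations from the group means correlated at 0.509 to 0.69 over the 6 pairs of mon and sibling libraries of the same clutch, over 10884 genes with a mean log2 CPM over 3. The highest correlation between different clutches was -0.193. Deviations within a group cancel out, so positive values within clutches force negative ones between clutches on average. The fit with clutch as a block added to the groups was an alternative. TMM factors lay between 0.967 and 1.042.

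In all 36 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 36 lists of a contrast, and again with a correlation estimated from the data. Of 988 gene names written in the lists, 31 matched no ID, 13 IDs were matched by a synonym and 158 by an orthologue symbol shared between copies. The lists held 980 genes, of which 28 were in more than one list, such as gfi1b, tal1 and klf17. Counts of called members are given over all genes and adjusted over the list alone. The grouping of lists into energy metabolism (11 lists), stress and growth (7 lists), other tissues (12 lists) and blood (6 lists) is for description.

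Named genes were trim33, the 10 risen and 10 fallen genes with the largest fold change at each stage, and up to 4 members of each list with the smallest p. The first 2 sets needed an adjusted p under 0.05, a mean of at least 1 CPM at that stage, the same direction in all 3 clutch pairs and a descriptive symbol. For the difference between stages the 5 genes of smallest p in each direction were taken, and for the stage comparison the 6 of largest fold change in each. Besides these, 15 genes were fixed in advance, among them gata1a, klf1, tal1, alas2, slc4a1a, spi1b, drl, kdrl, dhodh, coq2, pdss1, ahcy, epoa and cdkn1a, where slc4a1a and spi1b are found under SLC4A1 and SPI1. Some items chosen by these rules are not reported here. The text names part of the list members, and a list member outside the rule is named where a count of calls was 5 or fewer. All 19 genes whose effect differed between the stages are named. Those of them outside the rule, such list members, kgd4 and the genes under other observations were chosen after their values were seen.

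The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, removal of the 7 listed globins before scaling, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, an added threshold of 1 on the absolute log2 fold change, each comparison on its own 6 libraries, the clutch block, and each library left out in turn. For lists, fry, an estimated correlation, the block and DESeq2 size factors were used. Chosen after the data were seen were the fit of 6 libraries with the block, the fits without clutch 9, the counts without genes placed on the chromosome of trim33, and fry and the estimated correlation with the block. A named value was read as turned only where it was called in one of the fits, since uncalled values near 0 change sign freely. Single-gene comparisons of trim33 used an exact permutation test in Python 3.11.15 with SciPy 1.17.1. NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.

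The statistics were tested on simulated data, with counts drawn from the means, spread and sizes of the real libraries and with no clutch effect. At each stage 200 genes were changed, all with a mean of at least 1 CPM, and 21449 genes were tested. Recovery was thus not measured for genes below that level or for counts with clutch effects. At 22 hpf the edgeR test recovered 44% of genes changed 1.5-fold, 72% of those changed 2-fold, 100% at 4-fold and 96% at 8-fold, and 11 of its 167 calls (6.6%) were genes not changed. At 30 hpf it recovered 38%, 70%, 94% and 98%, and 9 of 159 calls (5.7%) were genes not changed. With the clutch block, on simulated counts that held no clutch effect, 18 of 169 calls at 22 hpf (10.7%) and 13 of 158 at 30 hpf (8.2%) were genes not changed. Camera called a simulated list raised 2-fold and did not call an unchanged one. Changes under 2-fold in a single gene were thus often missed at this depth and number of libraries.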

Results

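Red blood cell formation was compared between zebrafish moonshine mutants and their siblings by sequencing RNA from whole embryos. The moonshine line (mon) carries a mutation of trim33, the gene of the transcriptional cofactor TIF1γ, and its mutant embryos fail to form red blood cells. The siblings are labelled wild-type/het, so their pools may hold heterozygous carriers of the mutation and are not a pure wild-type baseline. Embryos were collected 22 and 30 hours post fertilization (hpf), and each library was made from a pool of 30 embryos of 1 phenotype from 1 clutch. Each of the 4 groups (mon and sibling at 22 hpf, mon and sibling at 30 hpf) held 3 libraries, 12 in all. Clutches 9, 11 and 13 gave the libraries at 22 hpf, and clutches 3, 4 and 9 gave those at 30 hpf. The embryos carried a green fluorescent reporter of the drl gene inherited from 1 parent, and mutants were told from their siblings by its weak signal. The series title names transcriptional control of energy metabolism in early erythropoiesis, so gene lists for metabolism were tested beside those for blood. Totals ranged from 18233320 to 23135676 gene counts per library, with 26261 to 26974 genes detected. Levels below are mean CPM (counts scaled to the TMM-adjusted library total) ± SD over 3 libraries, and log2 fold changes are mon over sibling ± SE unless another comparison is named. The SE was worked back from the test, as the absolute log2 fold change over the square root of the F statistic. It is thus approximate and may be too small where a group held few reads.

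The transcript of the mutated gene was lower in mutants at 22 hpf. At that stage trim33 (ENSDARG00000016181) stood at 50.7, 57.6 and 67.7 CPM in the mon libraries and at 85.7, 84.2 and 89.4 CPM in the sibling libraries. It fell by 0.56 ± 0.08 on the log2 scale (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00129). At 30 hpf the mon libraries held 72.8, 72.8 and 71.7 CPM and the sibling libraries 75.5, 76.3 and 78.0 CPM. The log2 fold change there was -0.08 ± 0.08 (edgeR, adjusted p = 1.0). An exact two-sided permutation test of trim33 alone gave p = 0.1 at each stage, the smallest value that 3 libraries against 3 allow. The change of the effect between the stages did not pass the test (log2 difference 0.48 ± 0.11, edgeR, adjusted p = 0.415). It passed with clutch as a block (edgeR, adjusted p = 1.41e-05) and without mon 22 hpf 13 (edgeR, adjusted p = 0.018). Without clutch 9 at either stage the call at 22 hpf was lost (edgeR, adjusted p = 0.0584). A mutated transcript need not be unstable, so these levels check the labels only in part.

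The comparison at 22 hpf asked which transcripts differ once the mutants can be recognised. Globin transcripts were nearly missing from the mutants. The beta-like embryonic globin hbbe3 (ENSDARG00000038147) stood at 0.949 ± 0.410 CPM in mon and 79.1 ± 1.48 CPM in siblings. It fell by 6.36 ± 0.22 on the log2 scale (edgeR, adjusted p = 3.91e-08). The alpha-like embryonic globin hbae3 (ENSDARG00000079305), at 113 ± 13.3 CPM in siblings, fell by 4.79 ± 0.20 on the log2 scale. No read of hbae5 (ENSDARG00000045142) was counted in mon, against 2.01 ± 0.0281 CPM in siblings, which makes it at least 41.3-fold lower with a floor of 3 counts over the group. All 14 globin genes together took 0.00107 ± 0.000198% of the counts in mon and 0.0352 ± 0.00338% in siblings. Reads of the near-identical globin copies may be split between them in the counting, so the values of single copies are uncertain.

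The fall extended over the machinery of red blood cells. The erythroid master regulator gata1a (ENSDARG00000013477) stood at 0.352 ± 0.186 CPM in mon and 6.55 ± 0.665 CPM in siblings, and it fell by 4.17 ± 0.35 on the log2 scale (edgeR, adjusted p = 2.1e-06). The transferrin receptor tfr1a (ENSDARG00000101322), which brings iron into erythroid cells, stood at 3.46 ± 0.523 against 74.2 ± 4.27 CPM (log2 -4.42 ± 0.11, edgeR, adjusted p = 8.75e-14). The gene of the first enzyme of erythroid heme synthesis, alas2 (ENSDARG00000038643), fell by 4.57 ± 0.23 (edgeR, adjusted p = 7.73e-08). Later enzymes of the pathway fell too, cpox by 2.27 ± 0.12 and urod by 1.46 ± 0.08 (edgeR, adjusted p = 4.6e-09 and 7.01e-09). In the gene order of the GRCz12tu assembly cpox lies within 100 placed genes of trim33. An effect of linked variants on cpox was thus not separated from a loss of red cells. The anion exchanger of the red cell membrane, SLC4A1 (ENSDARG00000012881), fell by 6.35 ± 0.28, while a second gene under this symbol (ENSDARG00000024560) had a log2 fold change of -0.86 ± 0.20 (edgeR, adjusted p = 2.12e-08 and 0.0936). That copy was called with clutch as a block (edgeR, adjusted p = 0.00354), without sibling 11 (adjusted p = 0.0351) and by DESeq2 (0.0267). The membrane skeleton gene epb41b fell by 5.55 ± 0.25 and the transcription factor gene gfi1b by 1.82 ± 0.22 (edgeR, adjusted p = 6.13e-10 and 0.000171). The erythroid factor klf1 fell by 2.95 ± 0.47 (edgeR, adjusted p = 0.00311), a call lost on the 6 libraries of 22 hpf alone (log2 -2.96, adjusted p = 0.153) and without clutch 9 (log2 -2.27, adjusted p = 0.156). The blood regulator tal1 stood at 21.5 ± 0.823 CPM in mon and 35.7 ± 2.92 CPM in siblings (edgeR, adjusted p = 0.161), and it was called with clutch as a block (edgeR, adjusted p = 6.17e-07), by edgeR on the 6 libraries of 22 hpf alone (0.00567), by DESeq2 (0.00962) and by limma-voom (0.0337). 

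Counted by list, 6 of 7 embryonic globins, 6 of 16 erythroid regulators, 5 of 23 genes of the erythroid membrane and enzymes and 11 of 37 genes of heme synthesis and iron were called lower at 22 hpf (edgeR quasi-likelihood over all genes). Adjusted over the list alone, the counts were 7, 10, 7 and 13. No member of these lists was called higher, and the block called 1 gene of heme synthesis and iron higher. The median log2 fold changes were -5.36, -0.45, -0.24 and -0.13, and the globin median was -5.36 also with hbae5 at its bound. Of the draculin genes, zinc finger genes of the early lateral mesoderm, 2 of 4 were lower (3 adjusted over the list alone), and drl itself fell by 2.28 ± 0.23 (edgeR, adjusted p = 1.94e-05). The mutants were sorted on a reporter of drl, so the fall of this gene is not independent of the sort. Of 11 genes of blood stem and hemogenic cells, 3 were lower (5 adjusted over the list alone), among them gfi1b and ikzf1. The other was myb, at log2 -0.54 ± 0.11 (edgeR, adjusted p = 0.0331), whose call was lost without any 1 of 5 libraries, with adjusted p from 0.0852 without sibling 9 to 0.154 without mon 9 (mon 11 and siblings 11 and 13 lay between). Of these 3 genes ikzf1 alone is not also in the list of erythroid regulators. The 6 lists stood below other genes, with Benjamini-Hochberg adjusted p (camera, preset correlation) from 2.37e-39 for the globins to 1.1e-07 for the blood stem list. With the clutch block and an estimated correlation the blood stem and draculin lists were not called at 22 hpf (adjusted p = 0.0751 and 0.0501).

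Genes outside the blood lists changed as well at 22 hpf, in both directions. The adhesion receptor gene adgrg11 (ENSDARG00000041413) stood at 5.95 ± 0.929 CPM in mon and 0.0845 ± 0.0781 CPM in siblings, and it rose by 6.04 ± 0.50 on the log2 scale (edgeR, adjusted p = 1.55e-06). PAPPA (ENSDARG00000101090), a protease of insulin-like growth factor binding proteins, stood at 47.6 ± 8.03 against 9.65 ± 1.80 CPM (edgeR, adjusted p = 1.32e-06). NCAN (ENSDARG00000005783), a proteoglycan of neural tissue, stood at 20.9 ± 1.78 against 6.56 ± 0.810 CPM, and the receptor phosphatase gene PTPRD (ENSDARG00000104937) at 40.4 ± 3.22 against 15.0 ± 1.45 CPM (edgeR, adjusted p = 1.09e-07 and 6.89e-08). The calcium pump gene atp2b2 rose by 2.42 ± 0.30 and the synaptic adhesion gene LRRTM4 (ENSDARG00000106522) by 3.15 ± 0.30 (edgeR, adjusted p = 0.000184 and 9.9e-06). The peroxidase gene epx, a marker of granulocytes, fell by 4.78 ± 0.41, and rfesd, a gene of an iron-sulfur domain protein, fell by 6.25 ± 0.50 (edgeR, adjusted p = 9.67e-06 and 1.01e-06). In all, 97 of 21778 genes were called at 22 hpf, 29 higher and 68 lower in mon (edgeR, adjusted p under 0.05), and 22 of the higher and 53 of the lower genes changed at least 2-fold. With clutch as a block the same fit called 322 genes, 138 higher and 184 lower, and all 97 were among them. Without clutch 9 the count was 60. The number of higher genes fell to 18 without sibling 11, and to 15 on the 6 libraries of 22 hpf alone.

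**Figure D1:**
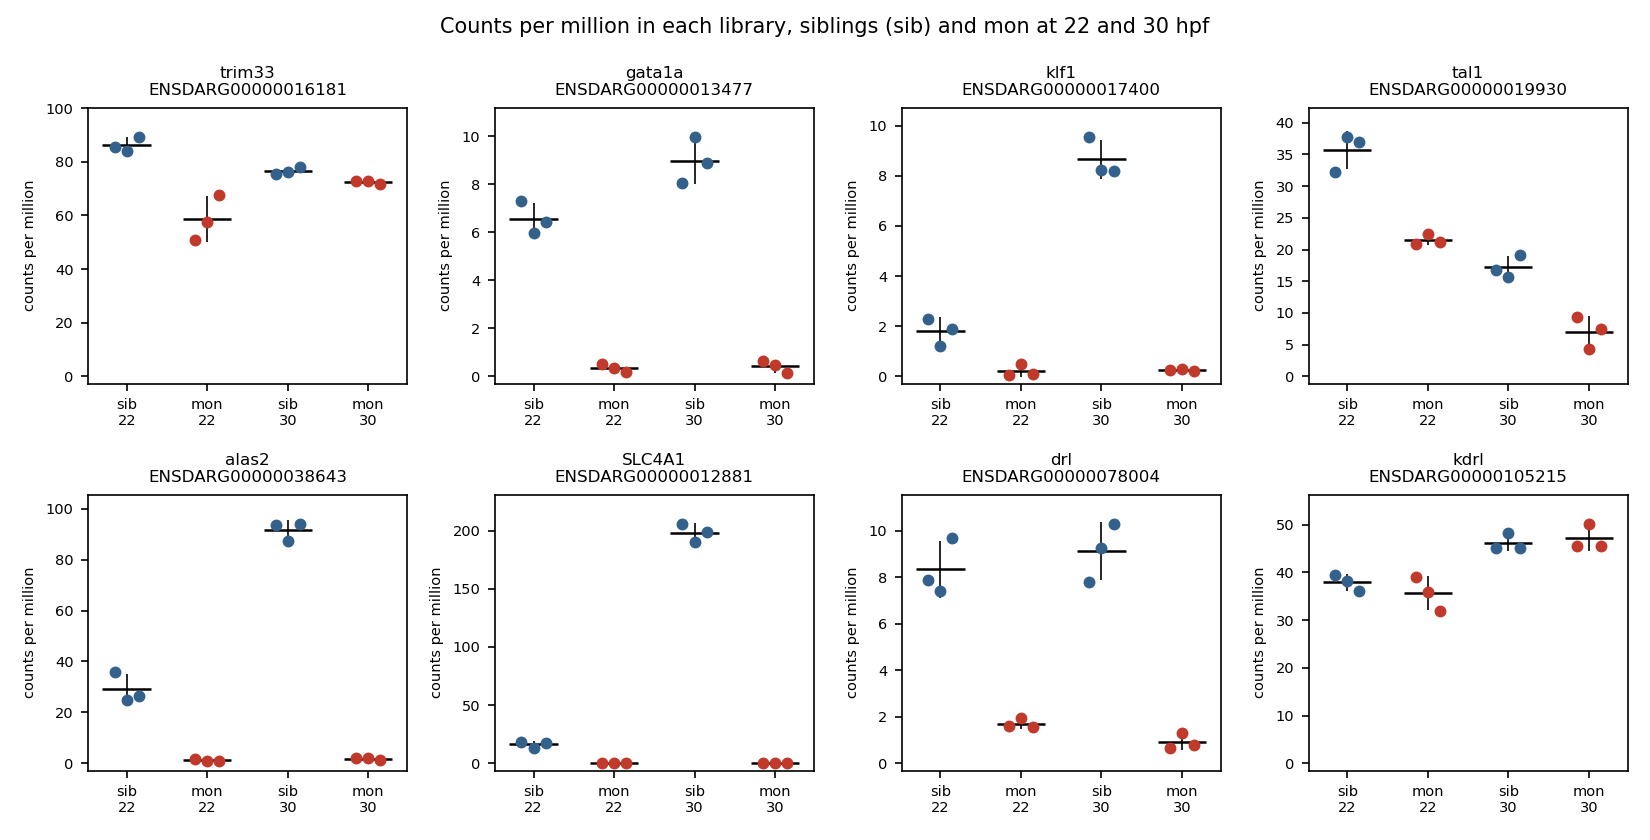
Levels in CPM in each library (linear axis; points are libraries, horizontal lines are group means and bars are SD over 3 libraries) for trim33, 5 blood genes (gata1a, klf1, tal1, alas2 and SLC4A1), drl and the endothelial gene kdrl in mon and sibling embryos at 22 and 30 hpf. The mon points of gata1a, klf1, alas2 and SLC4A1 lie near 0 at both stages, whereas trim33 differs by log2 -0.56 at 22 hpf and -0.08 at 30 hpf.

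At 30 hpf, when red blood cells of wild-type embryos are filling with hemoglobin, globin transcripts were again nearly missing from the mutants. The level of hbae3 was 1.24 ± 0.213 CPM in mon and 829 ± 30.2 CPM in siblings, and it fell by 9.38 ± 0.24 on the log2 scale (edgeR, adjusted p = 1.54e-08). For hbbe3 the levels were 0.503 ± 0.180 and 412 ± 72.8 CPM, and for hbae1.2 they were 0.0960 ± 0.0986 and 106 ± 8.62 CPM. No read of hbae4 was counted in mon, against 3.06 ± 0.233 CPM in siblings, which makes it at least 65.8-fold lower with the same floor. A globin gene named HBE1 (ENSDARG00000087390) fell by 9.58 ± 0.32 (edgeR, adjusted p = 2.2e-07). The 14 globin genes took 0.000347 ± 2.35e-05% of the counts in mon and 0.273 ± 0.00400% in siblings, with the same caution about shared reads.

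Regulators, heme enzymes and membrane genes were also lower at 30 hpf. The level of gata1a was 0.410 ± 0.257 CPM in mon and 8.97 ± 0.966 CPM in siblings, and klf1 stood at 0.247 ± 0.0258 against 8.67 ± 0.778 CPM (edgeR, adjusted p = 3.5e-07 and 1.05e-06). The blood regulator tal1 fell by 1.30 ± 0.19 (edgeR, adjusted p = 0.00263), a call lost on the 6 libraries of 30 hpf alone (adjusted p = 0.0547) and without clutch 9 (adjusted p = 0.296). For alas2 the levels were 1.74 ± 0.431 and 91.6 ± 3.94 CPM, and for urod 15.4 ± 1.03 and 93.8 ± 5.26 CPM. SLC4A1 (ENSDARG00000012881) stood at 0.396 ± 0.131 against 198 ± 7.98 CPM, and the second copy (ENSDARG00000024560) at 7.43 ± 1.46 against 10.5 ± 0.832 CPM (edgeR, adjusted p = 1.75e-11 and 0.533). With clutch as a block the second copy had an adjusted p of 0.0408 (edgeR). The nucleotidase gene nt5c2l1 fell by 2.00 ± 0.12, and hemgn, an erythroid nuclear protein gene, fell by 3.21 ± 0.29 (edgeR, adjusted p = 1.54e-08 and 3.54e-06). 

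All 7 embryonic globins, 7 of 16 erythroid regulators, 12 of 23 genes of the erythroid membrane and enzymes and 17 of 37 genes of heme synthesis and iron were called lower at 30 hpf (edgeR quasi-likelihood over all genes). Adjusted over the list alone, the counts were 7, 11, 15 and 19. No member of these lists was called higher, and with the block 1 gene of heme synthesis and iron was. The medians were -9.38 for the globins, also with hbae4 at its bound, -0.47 for the regulators, -0.70 for the membrane and enzymes and -0.28 for heme and iron. Of the 4 draculin genes, 3 were lower in both counts, and drl stood at 0.920 ± 0.356 against 9.11 ± 1.25 CPM, again not independent of the sort. Of the 11 blood stem and hemogenic genes, 4 were lower in both counts, among them gfi1b by 2.08 ± 0.22 and ikzf1, a lymphoid factor gene, by 3.03 ± 0.35 (edgeR, adjusted p = 2.85e-05 and 6.64e-05). The others were tal1 and lmo2, and of the 4 genes ikzf1 alone is not also in the list of erythroid regulators. The fall of this list is thus not separate from that of the regulators. Camera gave these 6 lists Benjamini-Hochberg adjusted p from 3.28e-48 for the globins to 8.78e-06 for the blood stem list. With an estimated correlation all 6 lists were called at both stages. With the clutch block and an estimated correlation the calls of the blood stem list (adjusted p = 0.146) and of the draculin list (0.0598) were lost at 30 hpf too.

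Other genes rose at 30 hpf, those with the largest fold changes from low levels. No read of ly6m2 was counted in siblings, against 2.30 ± 1.79 CPM in mon, which makes it at least 46.5-fold higher (edgeR, adjusted p = 0.00165). Fitted on the 6 libraries of 30 hpf alone it was not called (edgeR, adjusted p = 0.0836). The serpin gene serpinb1l4 stood at 3.60 ± 0.345 CPM in mon and 0.0966 ± 0.0504 CPM in siblings (edgeR, adjusted p = 1.48e-05). The level of LRRTM4 (ENSDARG00000106522) was 5.94 ± 1.31 against 1.60 ± 0.297 CPM, and neff2, a neurofilament gene, stood at 5.20 ± 1.40 against 1.51 ± 0.375 CPM (edgeR, adjusted p = 0.00041 and 0.00153). At this stage 172 of 21778 genes were called, 52 higher and 120 lower in mon (edgeR, adjusted p under 0.05), and 29 of the higher and 89 of the lower genes changed at least 2-fold. With clutch as a block 673 genes were called, 334 higher and 339 lower, and all 172 were among them. Without clutch 9 the count was 95, with 20 higher and 75 lower. The number of higher genes fell to 30 without sibling 3, 32 without sibling 4 and 34 without mon 4, and DESeq2 called 84.

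Few genes in the lists of energy metabolism were called in these whole embryos. A change confined to blood cells could be hidden by transcripts of other tissues, so such a change is not excluded by the values below. Across 11 lists with 335 tested genes for the respiratory complexes, their assembly, the mitochondrial genome and ribosome, the TCA cycle, coenzyme Q, pyrimidines, one-carbon metabolism and glycolysis, edgeR quasi-likelihood called 0 genes at 22 hpf. At that stage 7 of them had an unadjusted p under 0.05, DESeq2 and limma-voom called 0, and the clutch block called 1. The lists do not hold every gene of energy metabolism. Outside them kgd4 (ENSDARG00000079823), within 100 placed genes of trim33, was called lower at 22 hpf (log2 -0.67, edgeR, adjusted p = 0.0178). Its value at 30 hpf was -0.46 (edgeR, adjusted p = 0.165). With the block its adjusted p was 8.1e-06 at 22 hpf and 0.00295 at 30 hpf (edgeR). At 30 hpf edgeR called 1 of the 335, the folate enzyme gene aldh1l1, at 39.5 ± 1.86 CPM in mon and 51.3 ± 0.984 CPM in siblings (log2 -0.38 ± 0.08, adjusted p = 0.0317). Its call was lost without any 1 of the 6 libraries, with adjusted p from 0.0599 without mon 9 to 0.196 without mon 4. DESeq2 and limma-voom each called 1 of the 335 at 30 hpf, and the block called 13. Over all 21778 genes the block called 673 at 30 hpf, a slightly smaller share, and 322 at 22 hpf, a larger one. Among the 13 were 6 one-carbon genes, 3 higher and 3 lower. The block also called umps and cad, genes of pyrimidine synthesis, with log2 fold changes of 0.25 ± 0.07 and 0.14 ± 0.04. Their edgeR adjusted p was 0.283 and 0.301 without the block and 0.0023 and 0.000321 with it. Adjusted over the list alone, 2 pyrimidine genes were higher at 30 hpf.

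The pyrimidine enzyme gene dhodh, which feeds electrons to coenzyme Q, had log2 fold changes of -0.06 ± 0.14 at 22 hpf and -0.08 ± 0.15 at 30 hpf. The coenzyme Q genes coq2 and pdss1 had values of 0.05 ± 0.19 and 0.02 ± 0.15 at 22 hpf and of -0.32 ± 0.18 and 0.23 ± 0.15 at 30 hpf. The methionine cycle gene ahcy had -0.09 ± 0.07 and 0.01 ± 0.07. All of these had edgeR adjusted p = 1.0. Median log2 fold changes at 22 and 30 hpf were 0.02 and 0.02 for 38 complex I genes, -0.01 and 0.00 for 31 genes of complexes II to IV, 0.03 and 0.03 for 18 ATP synthase genes and 0.02 and 0.04 for 13 genes of the mitochondrial genome. They were 0.08 and 0.09 for 45 assembly factors, 0.00 and 0.01 for 27 TCA cycle genes, 0.02 and 0.02 for 14 coenzyme Q genes, 0.01 and 0.00 for 22 pyrimidine genes, -0.01 and 0.03 for 26 one-carbon genes and 0.00 and -0.02 for 30 glycolysis genes. None of these lists passed camera at either stage, with Benjamini-Hochberg adjusted p from 0.284 to 0.949. Without mon 13 the assembly factors were called at 22 hpf (camera, adjusted p = 0.0142). The 75 genes of the mitochondrial ribosome had medians of 0.04 and 0.06 and were called higher as a list at 30 hpf (camera, adjusted p = 0.0296), which was lost at adjusted p = 0.34 with an estimated correlation. That call was also lost without mon 4, mon 9, sibling 3 or sibling 9 (adjusted p = 0.306, 0.0669, 0.0714 and 0.167).

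Stress and growth programmes showed few calls. Over 7 lists with 237 genes, 2 were lower at 22 hpf, trim33 and the hypoxia list gene NDRG1 (ENSDARG00000032849, log2 -0.50 ± 0.11), and NDRG1 alone was lower at 30 hpf (-0.45 ± 0.10; edgeR, adjusted p = 0.0438 and 0.0476). The NDRG1 calls did not hold without single libraries: at 22 hpf adjusted p reached 0.272 without sibling 13, with sibling 11 the only library whose omission kept it, and at 30 hpf it was 0.0706 to 0.303 without any 1 of the 6 libraries. With the clutch block 7 of the 237 genes were called at each stage, among them 2 higher and 1 lower gene of the ATF4 list at 22 hpf and 3 higher and 1 lower at 30 hpf. DESeq2 called 4 and 2 of the 237, and limma-voom 1 and 1. Over all 21778 genes the block called 322 and 673, a smaller share at 22 hpf and a near one at 30 hpf. The cell cycle inhibitor cdkn1a had log2 fold changes of 0.29 ± 0.38 and 0.32 ± 0.42, and the erythropoietin gene epoa had 0.07 ± 0.32 and -0.15 ± 0.32 (edgeR, adjusted p = 1.0 for all). None of the 7 lists was called by camera, with adjusted p at 22 and 30 hpf of 0.659 and 0.359 for the ATF4 response and 0.522 and 0.949 for hypoxia. The values were 0.522 and 0.496 for DNA replication, 0.908 and 0.166 for interferon, 0.414 and 0.566 for the cytosolic ribosome and 0.659 and 0.319 for the TIF1 family and transcription elongation. Without mon 13 the hypoxia list was called at 22 hpf (camera, adjusted p = 0.013). For interferon at 22 hpf the median was -0.12 while the mean was 0.10.

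A few genes in the lists of other tissues were called. Over 12 lists with 272 genes, edgeR called 3 lower at 22 hpf: klf17, SLC20A1 (ENSDARG00000020114) of the pronephros list and the tight junction gene cldni. The factor klf17, of red cells and hatching gland, is also in the list of erythroid regulators. Copies can share the symbol SLC20A1, so it was not established that this ID is the pronephros copy. The block called 11 of the 272 at 22 hpf, DESeq2 5 and limma-voom 3. Over all 21778 genes edgeR called 97 and the block 322 at that stage, both a smaller share. SLC20A1 stood at 0.727 ± 0.157 against 3.27 ± 0.273 CPM at 22 hpf (edgeR, adjusted p = 0.00018). The value of cldni was -0.28 ± 0.06 (adjusted p = 0.0219), and its call was lost without any 1 of 5 libraries, with adjusted p from 0.0574 without mon 9 to 0.141 without sibling 9 (mon 11, mon 13 and sibling 11 lay between). At 30 hpf edgeR called klf17 alone, by -1.22 ± 0.13 (adjusted p = 2.26e-05), and with the block 23 of the 272 were called. Over all genes edgeR called 172 at 30 hpf, a larger share, and the block 673, a smaller one. The endothelial receptor kdrl had log2 fold changes of -0.09 ± 0.08 and 0.03 ± 0.08, and the myeloid factor SPI1 (ENSDARG00000000767) -0.35 ± 0.23 and -0.37 ± 0.24 (edgeR, adjusted p = 1.0 for all). As lists, endothelium and neutrophil and mast cell genes stood lower at 22 hpf (camera, adjusted p = 0.0337 and 0.025). These became adjusted p = 0.076 and 0.0855 with an estimated correlation, and endothelium 0.0552 with the block. Lens and retina genes stood higher at 22 hpf (0.0459, adjusted p = 0.647 with an estimated correlation, 0.116 with the block), and at 30 hpf they were not called (0.108). The block called them lower at 30 hpf (0.0371, and 0.425 with an estimated correlation as well), as did the fit without mon 9 (0.00374). Neuronal genes stood lower at 30 hpf (camera, adjusted p = 0.0137; adjusted p = 0.434 with an estimated correlation). Omitting single libraries also ended these calls. At 22 hpf endothelium was lost without mon 11 (0.119), mon 13 (0.0711) or sibling 9 (0.159), and neutrophils without mon 11 (0.0531), mon 13 (0.11) or sibling 9 (0.159). Lens was lost without mon 13 (0.405), sibling 9 (0.121) or sibling 11 (0.446), and neurons at 30 hpf without mon 4 (0.352) or sibling 9 (0.157).

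The remaining tissue lists were not called by camera at either stage in the fit of all libraries. Camera's adjusted p at 22 and 30 hpf was 0.39 and 0.911 for macrophages, 0.243 and 0.319 for the pronephros, 0.259 and 0.699 for the heart and 0.544 and 0.359 for skeletal muscle. It was 0.498 and 0.319 for notochord and hatching gland, 0.498 and 0.639 for epidermis, 0.522 and 0.355 for pigment cells and 0.659 and 0.319 for the yolk syncytial layer and liver. Endothelium had adjusted p = 0.508 at 30 hpf, neutrophils and mast cells 0.566 and neurons 0.171 at 22 hpf (camera). Leaving out single libraries at 22 hpf brought some to a call. Without mon 9 these were neurons (0.0332), pigment cells (0.0409), skeletal muscle (0.0182) and epidermis (0.0416), and without sibling 13 pigment cells (0.0078). The rotation test fry, which does not compare a list with other genes, called heart (adjusted p = 0.00687) and pronephros (0.0173) lower at 22 hpf, and yolk and liver genes (0.0299) lower at 30 hpf. With the block fry gave 0.0149 and 0.00765 for the first lists, and it called notochord and hatching gland (0.0405) lower at 30 hpf, while yolk and liver had 0.0538.

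**Figure D2:**
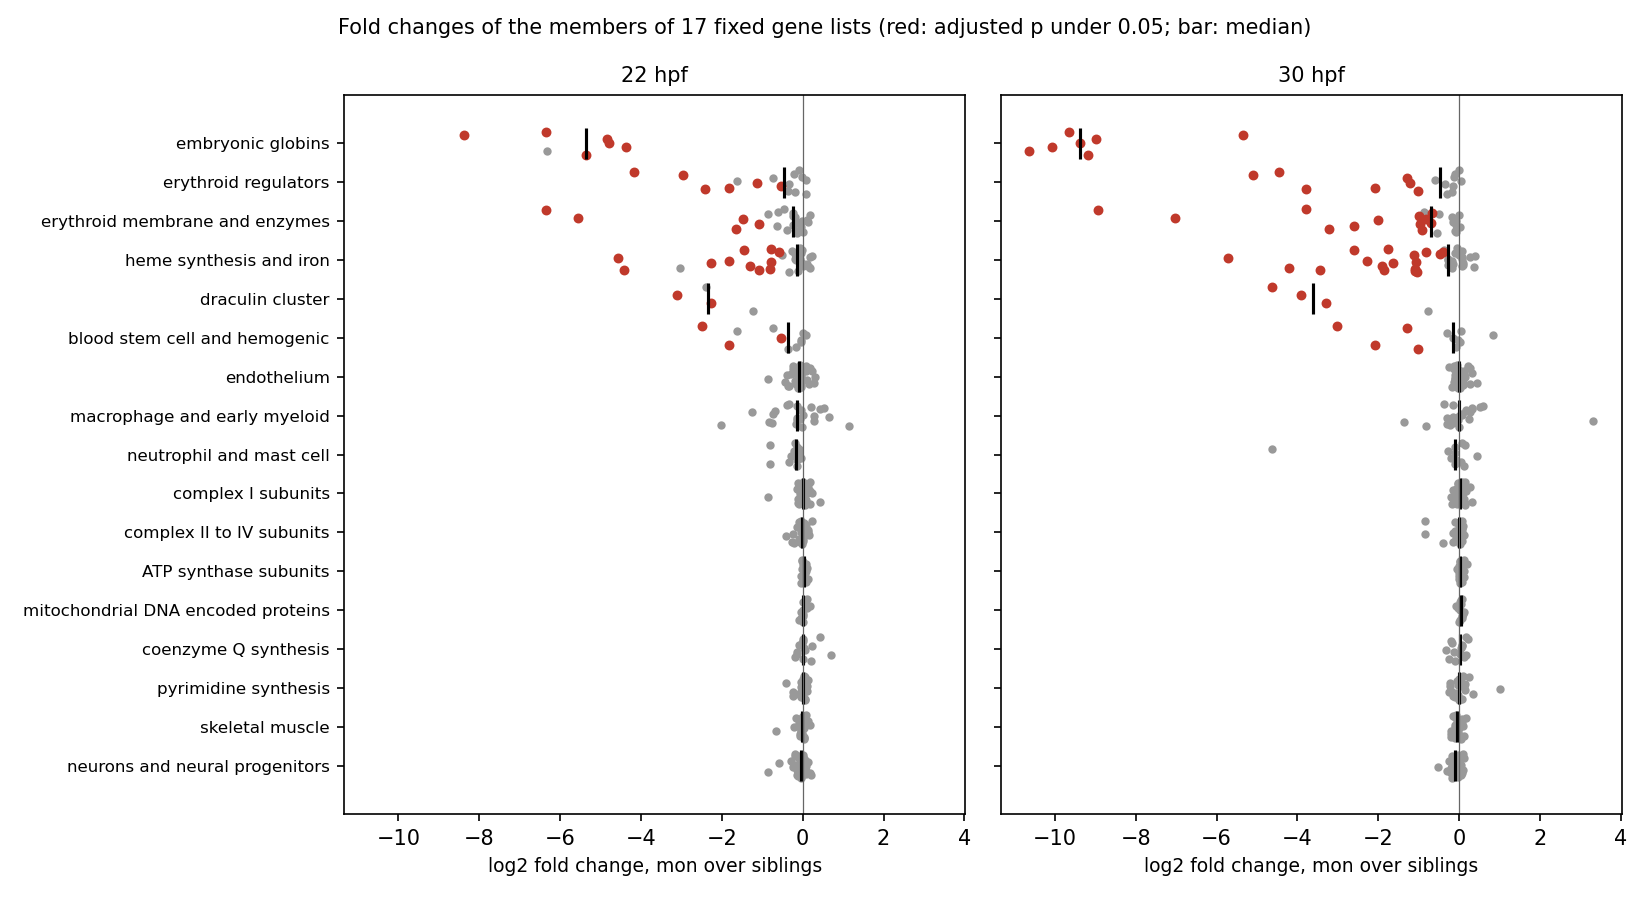
Log2 fold change of mon over sibling (x axis) for each tested gene of 17 lists (y axis) at 22 and 30 hpf, with called genes in red and the list median as a bar. The medians of the globins lie at -5.36 and -9.38, and those of the metabolic lists drawn lie close to 0.

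The effect of the mutation on 19 genes differed between 30 and 22 hpf, 4 toward higher and 15 toward lower values (edgeR interaction term, adjusted p under 0.05). Fibronectin, FN1 (ENSDARG00000006526), stood at 533 ± 38.5 CPM in siblings and 563 ± 49.3 CPM in mon at 22 hpf, and at 90.6 ± 6.24 and 203 ± 16.3 CPM at 30 hpf. Its log2 difference of effects was 1.08 ± 0.11 (edgeR, adjusted p = 0.000167). The gamma subunit of the muscle acetylcholine receptor, chrng, had levels of 27.4 ± 4.80 CPM in siblings and 29.5 ± 2.83 CPM in mon at 22 hpf. At 30 hpf it stood at 7.56 ± 1.42 CPM in siblings, with a log2 fold change of 1.40 ± 0.14 in mon (edgeR, adjusted p = 0.00783 for the difference). The granulocyte gene epx went the same way, with 18.5 ± 4.02 CPM in siblings and 12.7 ± 3.04 CPM in mon at 30 hpf against 5.10 ± 1.62 and 0.180 ± 0.0719 CPM at 22 hpf (edgeR, adjusted p = 0.0011). The T-box gene tbx16l, of the presomitic mesoderm, stood at 21.7 ± 2.68 and 21.1 ± 1.77 CPM at 22 hpf, and at 4.46 ± 1.08 CPM in siblings and 0.555 ± 0.152 CPM in mon at 30 hpf (log2 difference -2.95 ± 0.29, edgeR, adjusted p = 9.25e-05). The nucleotidase nt5c2l1 was at 26.0 ± 2.05 and 28.0 ± 2.11 CPM at 22 hpf and at 27.0 ± 3.69 and 6.77 ± 0.369 CPM at 30 hpf (edgeR, adjusted p = 8.9e-06). For NCAN the siblings rose to 44.9 ± 2.78 CPM at 30 hpf, beside 42.3 ± 3.49 CPM in mon (log2 difference -1.76 ± 0.15, edgeR, adjusted p = 2e-05). Among blood genes, the effect on urod deepened by -1.14 ± 0.11 and that on hbae1.2 by -5.71 ± 0.57, whereas that on tfr1a lessened by 0.98 ± 0.14 (edgeR, adjusted p = 8.47e-05, 9.66e-05 and 0.00672).

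By list, 3 of 7 globins, 2 of 23 membrane and enzyme genes and 2 of 37 heme and iron genes had a deeper fall at 30 hpf, and 1 heme and iron gene a lesser one (edgeR; 5, 8 and 4 deeper, and 0, 1 and 2 lesser, adjusted over the list alone). The 3 lists were called as lists (camera, Benjamini-Hochberg adjusted p = 1.03e-21, 1.82e-08 and 0.000208) and also with an estimated correlation (adjusted p = 0.000255, 0.00261 and 0.0148). With the clutch block and an estimated correlation these calls were lost (adjusted p = 0.059, 0.0853 and 0.137). No gene of the 335 of energy metabolism was called by the edgeR interaction term, with 7 at an unadjusted p under 0.05 and 0 by DESeq2, limma-voom or the block. With clutch as a block 105 genes differed over the whole table, and without clutch 9 the count was 9. Only clutch 9 was collected at both stages, so a stage effect and a difference between clutches are only partly separable.

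The genes called at the 2 stages overlapped. Of 29 genes higher at 22 hpf and 52 higher at 30 hpf, 7 were shared, against 0.0692 expected from independent lists (Fisher's exact test, p = 4.36e-13). Of 68 and 120 lower genes, 52 were shared, against 0.375 expected (Fisher's exact test, p = 1.06e-108), and 0 genes were called in opposite directions. Across the 210 genes called at either stage, the log2 fold changes at 22 and 30 hpf correlated with Pearson's r = 0.84 and Spearman's rho = 0.85. Outside the 4 erythroid lists, 166 such genes gave r = 0.80 and rho = 0.83, and 155 of them (93.4%) had the same sign. Over all 21778 genes r was 0.43 and rho 0.13. Genes are not independent replicates, so the correlations describe the libraries and carry no p. Fisher's test treats genes as independent, so its p-values for the overlap may overstate the evidence. The stages share no library, although clutch 9 gave libraries to both, and without clutch 9 the shared genes were 3 higher and 35 lower. With clutch as a block 59 higher and 108 lower genes were shared, and 1 gene higher and 1 gene lower at 22 hpf were called in the opposite direction at 30 hpf.

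**Figure D3:**
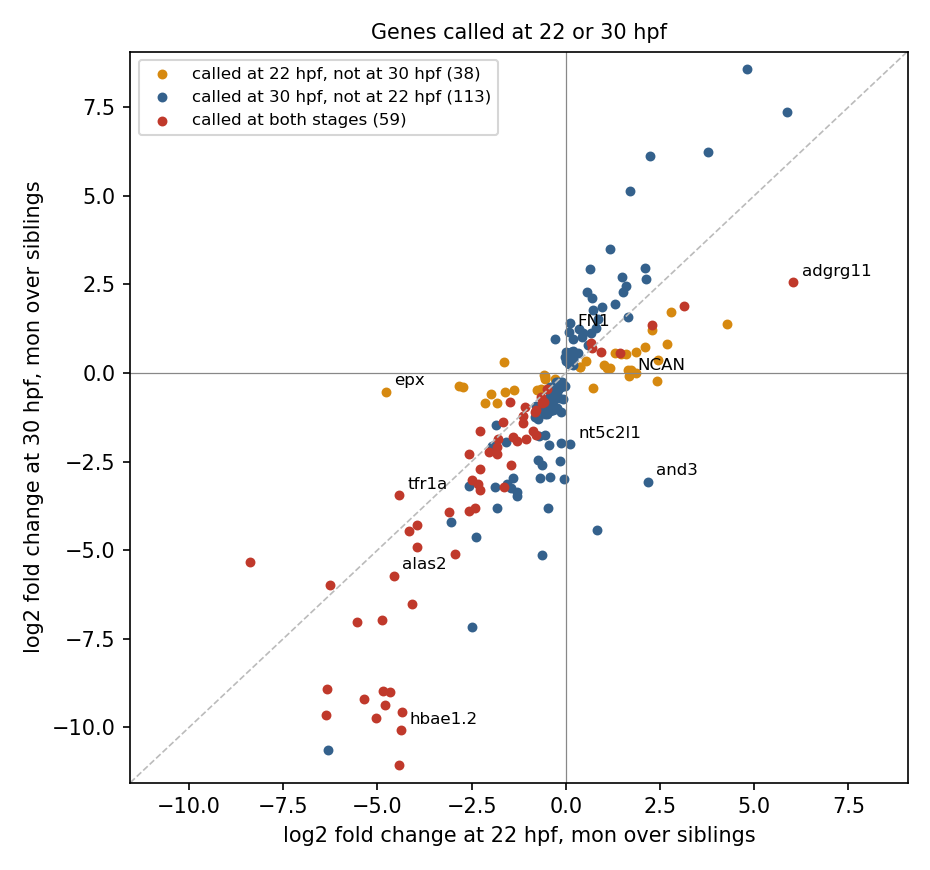
Log2 fold change of mon over sibling at 22 hpf (x axis) against 30 hpf (y axis) for each called gene, coloured by the stage at which it was called. Of 210 genes, 59 were called at both stages, 38 at 22 hpf and not at 30 hpf, and 113 at 30 hpf and not at 22 hpf.

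Normal development over the same 8 hours served as the background. In siblings the muscle genes pvalb1 (parvalbumin) and XIRP2 (ENSDARG00000091090) rose from 0.626 ± 0.155 to 379 ± 20.8 CPM and from 0.134 ± 0.103 to 117 ± 12.7 CPM (edgeR, adjusted p = 3.18e-14 and 1.07e-12). Genes of the presomitic mesoderm fell, tbx6 from 78.6 ± 6.70 to 2.03 ± 0.151 CPM and msgn1 from 31.4 ± 5.85 to 0.999 ± 0.187 CPM (edgeR, adjusted p = 2.65e-15 and 1.98e-11). In mon, tbx6 fell by 5.27 ± 0.11 on the log2 scale as it did in siblings, and pvalb1 rose by 9.69 ± 0.17 (edgeR, adjusted p = 2.06e-15 and 3.44e-14). By list, 21 of 25 skeletal muscle genes, 28 of 34 neuronal genes, 22 of 30 glycolysis genes and 21 of 38 complex I genes rose in siblings (edgeR over all genes). Of the blood lists, 5 of 7 globins and 17 of 23 membrane and enzyme genes rose in siblings, and 11 heme and iron genes rose while 9 fell. Among erythroid regulators 2 rose and 7 fell, and 4 blood stem genes and 3 of 4 draculin genes fell. With the clutch block 3 regulators rose and 6 fell, and 2 blood stem and 0 draculin genes fell, so the draculin calls were lost. In all 9391 genes changed in siblings, 4873 up and 4518 down, and 9202 in mon, 4804 up and 4398 down (edgeR, adjusted p under 0.05). Of these, 2781 rose and 922 fell at least 2-fold in siblings, and 2678 rose and 833 fell at least 2-fold in mon. Clutch and stage were largely confounded here, since clutch 9 alone was collected at both stages.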

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

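The tests chosen only after the result was seen are the count of calls around trim33, the tests of the erythroid genes against sibling levels at 22 hpf and of the summed globins, the splits, the fits without clutch 9, and fry or an estimated correlation with the block.

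The results below stand out because the effect of the mutation differed between 30 and 22 hpf by a test of the difference itself (edgeR interaction term, adjusted p under 0.05). Toward higher values at 30 hpf, the log2 difference of effects was 1.08 for FN1 (ENSDARG00000006526), 4.25 for epx, 0.98 for tfr1a and 1.29 for chrng. Toward lower values it was -2.10 for nt5c2l1, -1.76 for NCAN (ENSDARG00000005783), -1.14 for urod, -2.95 for tbx16l and -5.71 for hbae1.2. It was -4.59 for hbae3, -2.64 for atp2b2 and -0.87 for PTPRD (ENSDARG00000104937). The red cell carbonic anhydrase gene cahz had -3.34 (edgeR, adjusted p = 0.00473), with 26.8 CPM in siblings and 19.5 CPM in mon at 22 hpf and 67.1 and 4.83 CPM at 30 hpf. Without clutch 9 at either stage the adjusted p of these differences was 0.364 for atp2b2, 0.24 for PTPRD, 0.208 for epx, 0.109 for hbae3, 0.0985 for chrng and 0.066 for tfr1a (edgeR). Limma-voom did not call epx (adjusted p = 0.37) or tfr1a (0.18).

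Further differences were called but ended without single libraries. Limma-voom did not call hbbe3 (adjusted p = 1.0), ERBB4 (0.861), and3 (0.18) or fech (0.0639), and without clutch 9 edgeR did not call hbbe3 (0.791), ERBB4 (0.693), fech (0.638) or TNC (0.0675). The actinodin gene and3, of the fin fold, had -5.25 (edgeR, adjusted p = 0.00783, and 0.0734 without mon 22 hpf 11). HBE1 (ENSDARG00000087390) had -5.23 (adjusted p = 0.00873, and 0.0577 without mon 22 hpf 11). For hbbe3 the value was -3.29 (adjusted p = 0.0136), with 0.107 without mon 22 hpf 11, 0.0676 without mon 30 hpf 4 and 0.0567 without mon 22 hpf 9. It was 0.0519 without mon 30 hpf 9, and 0.0544, 0.057 and 0.053 without siblings 11, 13 and 9 of 22 hpf. With no filter on low counts it was 0.0631.

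The ferrochelatase gene fech had -0.97 (edgeR, adjusted p = 0.0161). Its adjusted p was 0.0554 and 0.0666 without mon 4 and 9 of 30 hpf, 0.057 and 0.059 without siblings 13 and 9 of 22 hpf, and 0.083 and 0.0681 without siblings 3 and 9 of 30 hpf. The tenascin gene TNC (ENSDARG00000078362) had -1.14 (edgeR, adjusted p = 0.0147). Its adjusted p was 0.0635 without mon 22 hpf 11, 0.0567 and 0.0666 without mon 3 and 9 of 30 hpf, 0.0731 and 0.0664 without siblings 11 and 13 of 22 hpf, and 0.063 and 0.0692 without siblings 4 and 9 of 30 hpf. The neuregulin receptor gene ERBB4 (ENSDARG00000090408) had -1.88 (edgeR, adjusted p = 0.0322). Its adjusted p was 0.11 without mon 22 hpf 13, 0.0971, 0.0733 and 0.0666 without mon 3, 4 and 9 of 30 hpf, 0.197 and 0.165 without siblings 13 and 9 of 22 hpf, and 0.0747 and 0.0965 without siblings 4 and 9 of 30 hpf.

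Among lists, the difference between the stages had adjusted p = 1.03e-21 for the globins, 1.82e-08 for the erythroid membrane and enzymes and 0.000208 for heme synthesis and iron (camera, all toward lower values at 30 hpf). With the block and an estimated correlation these became 0.059, 0.0853 and 0.137. Endothelium differed toward higher values (camera, adjusted p = 0.0296). It did not with an estimated correlation (0.102), with fry (0.122), or with the block and either of these (0.283 and 0.0533). That call also ended without mon 11 or 13 of 22 hpf (0.0917 and 0.0586), mon 3 or 4 of 30 hpf (0.215 and 0.0837), sibling 9 of 22 hpf (0.14) and siblings 3 or 9 of 30 hpf (0.0532 and 0.165). Erythroid regulators differed toward lower values (camera, adjusted p = 0.0296). They did not with an estimated correlation (0.184), with fry (0.122), with the block (0.0552), or with the block and either of the former (0.295 and 0.0926). That call also ended without mon 11 or 13 of 22 hpf (0.0917 and 0.0832), mon 4 of 30 hpf (0.157), siblings 9 or 13 of 22 hpf (0.213 and 0.065) and siblings 3, 4 or 9 of 30 hpf (0.0532, 0.084 and 0.0633). Lens and retina differed toward lower values (camera, adjusted p = 0.00229). They did not with an estimated correlation (0.524), with fry (0.458), or with the block and either of these (0.354 and 0.141), nor without mon 22 hpf 13 (0.054) or mon 30 hpf 4 (0.0837).

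Genes called lower in the 4 erythroid lists at 30 hpf numbered 43. Pools of mon younger than their siblings would leave mon at 30 hpf between the sibling levels of 22 and 30 hpf, but 74.1% of the 27 such genes that rose in siblings (20 genes) stood in mon below the sibling 22 hpf mean. Reads shared between near-identical globin copies would leave the summed globin share alone, but it fell in all 6 clutch pairs, the least with a log2 change of -4.89. Missing or immature red cells may underlie the lower levels, a hypothesis that was not itself tested, from pools sorted on a blood reporter.

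Changes at 30 hpf outside the erythroid lists comprised 129 called genes. A difference in age between mon and sibling pools would shift these genes along the change that siblings made between the stages. The fitted shifts were -0.042, -0.068 and -0.017 of that change in clutches 3, 4 and 9, and taking them out left a median of at least 0.98 of the mon change in each clutch. Of the 129 genes 65.9 to 69.8% went against the sibling stage change in each clutch, against 44.9 to 50.7% of 69 genes at 22 hpf, which leaves a delay of part of these genes open. One common shift in age is thus argued against as the whole source, while an indirect effect of missing blood may remain and was not tested.

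Calls around trim33 were counted among the genes that could be placed in the gene order of the GRCz12tu assembly. Higher calls numbered 2 at 22 hpf and 4 at 30 hpf, against 0.184 and 0.353 expected. These are 10.9 and 11.3 times the number expected (Fisher's exact test, p = 0.014 and 0.000387). Lower calls numbered 2 and 1, against 0.282 and 0.762 expected, or 7.08 and 1.31 times (Fisher's exact test, p = 0.0319 and 0.537). The ratios thus rest on very few genes. With clutch as a block, 10 of 75 higher calls at 22 hpf lay within 100 placed genes on either side, erythroid lists left out, which was 9.44 times the number expected (Fisher's exact test, p = 9.37e-08). Over the 198 genes of that window the log2 fold changes at 22 and 30 hpf correlated with Spearman's rho = 0.48, against at most 0.41 in 97 windows on other chromosomes. With the block the whole chromosome of trim33 held 26 of 75 higher calls at 22 hpf and 32 of 226 at 30 hpf. These were 8.05 and 3.29 times the number expected (Fisher's exact test, p = 2.53e-17 and 2.76e-09). Lower calls there were 2.37 and 1.17 times the number expected (Fisher's exact test, p = 0.0133 and 0.595). The excess of higher calls was thus not confined to the window. All these checks are void, because the 64.7% of tested genes that could be placed by name fall short of the 80% required, and the assembly is not that of the counts. A loss of RNA from nearby erythroid genes does not by itself give higher calls, whereas variants linked to the mon allele and local effects of losing trim33 cannot be told apart here.

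Splits of 6 libraries into 3 and 3 number 10, so the share of splits with a result as large is never under 0.1. In each comparison only 1 split, the real one, called as many genes. At 22 hpf the real split called 97 genes and the highest other 5, and at 30 hpf the values were 172 and 0. From 22 to 30 hpf they were 9391 and 0 in siblings and 9202 and 0 in mon. For the difference between stages, in a fit of the clutch pairs as a block, they were 105 and 3. Among the splits that part all 3 clutch pairs, the other 3 at each stage called 0 genes with edgeR, and the split with 5 calls at 22 hpf parts 1 pair.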

How the results depend on the processing

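The fits of 6 libraries with the block, the fits without clutch 9, the counts without the chromosome of trim33, and fry and the estimated correlation with the block were chosen only after the result was seen, except that the overlap without clutch 9 was planned. ERCC scaling was not run, since the table held 0 ERCC lines, and the difference between stages has no fit on its own 6 libraries.

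The number of genes changed at 22 hpf (97) became 322 with the clutch block, 63 on its own 6 libraries, 357 on these with the block, 60 without clutch 9 and 155 with DESeq2. At 30 hpf the 172 genes became 673 with the block, 745 on 6 libraries with the block and 95 without clutch 9. The 19 differences between stages became 105 with the block, 9 without clutch 9 and 33 with DESeq2. The block's calls held all 97, 172 and 19. Stage counts became 3703 in siblings and 3511 in mon with a log2 threshold of 1, which by construction passes fewer genes. Other totals stayed within 1.5 times. Shared genes became 59 higher and 108 lower with the block and 3 higher without clutch 9. Leaving out clutch 9 also removes libraries, and the block takes out differences between clutches; beyond that the cause was not tested. With single libraries left out the counts ran from 75 to 95, 121 to 132, 16 to 21, 8240 to 8766 and 8036 to 8436, in the order 22 hpf, 30 hpf, difference, siblings and mon.

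List calls that ended with an estimated correlation had adjusted p at 22 hpf of 0.076 for endothelium, 0.647 for lens and retina and 0.0855 for neutrophils, at 30 hpf of 0.34 for the mitochondrial ribosome and 0.434 for neurons, and for the difference of 0.102 for endothelium, 0.184 for regulators and 0.524 for lens. With fry the values were 0.547 (lens) and 0.0823 (neutrophils) at 22 hpf, 0.187 (mitochondrial ribosome) and 0.203 (neurons) at 30 hpf, and 0.122 (endothelium), 0.122 (regulators) and 0.458 (lens) for the difference. With fry and the block they were 0.266, 0.0703, 0.0534, 0.15, 0.0533, 0.0926 and 0.141 in that order. The block alone ended endothelium (0.0552) and lens (0.116) at 22 hpf and the regulators' difference (0.0552). The block with an estimated correlation ended blood stem genes (0.0751 at 22 hpf, 0.146 at 30 hpf) and draculin genes (0.0501 and 0.0598). At 22 hpf it also ended endothelium (0.199), lens (0.553) and neutrophils (0.178), and at 30 hpf the mitochondrial ribosome (0.201) and neurons (0.423). Of the differences it ended globins (0.059), endothelium (0.283), membrane (0.0853), regulators (0.295), heme (0.137) and lens (0.354). The cause was not tested.

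Without single libraries the adjusted p of camera at 22 hpf ran from 9.22e-08 to 7.24e-05 for blood stem genes, 1.99e-10 to 9.7e-07 for draculin genes, 5.49e-35 to 3.05e-31 for globins, 2.69e-13 to 1.53e-09 for membrane genes, 8.73e-15 to 5.63e-12 for regulators and 2.18e-17 to 6.82e-14 for heme. At 30 hpf the same lists gave 3.91e-06 to 0.000638, 1.17e-08 to 8.45e-07, 1.19e-49 to 4.81e-42, 9.63e-30 to 5.24e-27, 3.22e-21 to 2.79e-18 and 1.09e-25 to 2.87e-24. Differences ran from 1.94e-26 to 1.43e-17 for globins, 1.29e-08 to 3.61e-06 for membrane genes and 0.000112 to 0.0087 for heme.

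Other list calls ended without single libraries. Endothelium at 22 hpf ran from 0.026 to 0.159 and ended without mon 11 (0.119), mon 13 (0.0711) and sibling 9 (0.159). Lens at 22 hpf ran from 0.000265 to 0.446 and ended without mon 13 (0.405), sibling 9 (0.121) and sibling 11 (0.446). Neutrophils at 22 hpf ran from 0.00853 to 0.159 and ended without mon 11 (0.0531), mon 13 (0.11) and sibling 9 (0.159). The mitochondrial ribosome at 30 hpf ran from 0.00332 to 0.306 and ended without mon 4 (0.306), mon 9 (0.0669), sibling 3 (0.0714) and sibling 9 (0.167). Neurons at 30 hpf ran from 0.0007 to 0.352 and ended without mon 4 (0.352) and sibling 9 (0.157). Lists uncalled with all libraries gained 9 calls without single libraries, and 3 each with fry and with fry and the block. Among the former, pigment cells differed between the stages without sibling 22 hpf 9 (0.0122). Differences ran from 0.00946 to 0.215 for endothelium, 0.00718 to 0.213 for regulators and 1.07e-05 to 0.0837 for lens.

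Among 148 values of named genes, which leave out kgd4, only 1 reversed. It was that of the signal recognition particle RNA gene Metazoa_SRP (ENSDARG00000089201), among the 6 genes with the largest fall from 22 to 30 hpf. In mon its log2 change was -5.63 (edgeR, adjusted p = 0.0413) and 0.33 with the block (0.805). Only clutch 9 was collected at both stages, so with the block a change between stages can be read only through clutch 9. The call in mon also ended without mon 11 (0.0934) or mon 13 (0.0892) of 22 hpf and mon 3 (0.112), mon 4 (0.111) or mon 9 (0.109) of 30 hpf. Limma-voom (0.439) and edgeR with no filter on low counts (0.0559) ended it too. In siblings limma-voom did not call this gene (adjusted p = 0.327). Leaving out siblings 11 or 13 of 22 hpf, or 3, 4 or 9 of 30 hpf, also ended that call (edgeR, adjusted p from 0.0685 to 0.0957). Of 148 values of named genes the block brought 14 to a call and ended 1 more, that of Metazoa_SRP in siblings. Beside the 3 list calls it ended, given above, it called lens and retina at 30 hpf (0.0371). It changed no other call among these 148 values or among the lists tested with camera. Counts of list members called from 22 to 30 hpf did change, such as lower draculin genes in siblings, from 3 to 0. Over the alternatives other than leaving out single libraries, 931 values of called genes kept direction and call, 44 lost the call and 1 reversed. With single libraries left out 667 kept direction and call and 71 lost the call. The cause was not tested.

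Depth and the number of libraries limit single genes with small changes or few reads, so an uncalled gene is not shown to be unchanged. In RNA of whole embryos a change confined to blood cells can also be hidden by other tissues.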

Other observations

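The tests reported in this part are those of the report's fits, on genes chosen only after the result was seen.

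Of genes outside the lists, JUNB (ENSDARG00000104773) rose at 30 hpf by 1.52 on the log2 scale, with 7.01 CPM in siblings (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000243). The genes fosl2, SOCS3 (ENSDARG00000026611) and il6st had log2 fold changes at 30 hpf of 0.96, 1.13 and 0.63 (edgeR, adjusted p = 0.00049, 0.000498 and 0.000535). The actinodin genes and1 and and2 fell at 30 hpf by 1.78 and 2.07 on the log2 scale (edgeR, adjusted p = 3.5e-07 and 9.81e-06). The basement membrane gene FREM2 (ENSDARG00000076856) fell by 0.66 at 22 hpf and 0.67 at 30 hpf (edgeR, adjusted p = 7.49e-05 and 2.94e-05).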
